A study of Mus musculus with 12 samples.

How the data were processed

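Lung tissue of male C57BL/6 mice aged 6 to 8 weeks was profiled by RNA sequencing in 12 libraries, 4 from a Control group, 4 from a Model group given bleomycin and 4 from an HBG group given bleomycin and Huashibaidu granules. Per the labels' protocols, polyadenylated RNA was selected, libraries were made with a TruSeq stranded kit and sequenced as paired reads of 150 bases. Group and replicate number were taken from the sample titles, where the HBG libraries carry the abbreviation HSBD.

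The values used are estimated counts per gene, deposited in a single table for the series. The header does not name the unit. It was read from the values: between 10% and 15.1% of the values of a library were not whole numbers, and library sums differed, as an estimator that divides reads among genes gives. Per the submitters' processing notes, FastQC 0.11.9, Trimmomatic 0.39, cutadapt, fastp, STAR 2.7.9a, HISAT2, featureCounts 2.0.1, HTSeq and DESeq2 1.34.0 were named, with no role or order, together with the builds GRCm39 and mm10. Which tool made the counts, and on which annotation, is not given in the sources used here, so no coordinates are printed and reads of near-identical genes may be divided differently between libraries. The table also holds group means, which differed from the means of the 4 libraries by at most 7e-12 and were not used, and a gene length, which was used for checks of length.

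The estimated counts were rounded to whole numbers. The table lists 56980 genes, of which 22353 had 0 counts in all 12 libraries. Totals per library ranged from 17979908 to 27150874. A count of 0 in a library allows up to 3 counts, which corresponds to 0.117 to 0.166 CPM (counts scaled to the library total). Such floors cover counting error only, since the reads carry no molecular identifiers. Libraries of a group were compared in pairs before use: correlations of log2 CPM ranged from 0.925 to 0.984 and the chi-square statistic per degree of freedom from 17.9 to 157, so no pair agreed within sampling noise.

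Expression was tested with edgeR 4.0.16 in R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8). Counts were scaled by TMM, genes were filtered with filterByExpr, which kept 17827, and the quasi-likelihood F test was fitted to all 12 libraries with the group as the only term. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Means and SDs are CPM with the TMM factors. Standard errors of log2 fold changes were derived from the F statistic. The 3 comparisons were Model against Control, HBG against Model and HBG against Control. Genes past the threshold in both of the first 2, with opposite signs, were counted too.

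Before the data were examined, 60 gene lists were fixed from textbook knowledge of lung cell types, fibrosis pathways, other tissues and RNA quality. Each had at least 5 tested members and was tested with limma's camera on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 60 lists. The lists were tested again with the correlation estimated per list, and with fry. A list score is the mean log2 CPM of a list's tested members in a library, relative to the mean library. Genes named in the text follow a rule fixed at the same time. It takes 18 key genes of fibrosis and lung cells whether or not they passed. It adds the 6 highest and 6 lowest fold changes among genes past the threshold that reached 1 CPM and separated the groups. Predicted or clone names, immunoglobulin and T cell receptor segments and pseudogenes were left out there, so larger fold changes can exist. From each of the 8 lists of smallest adjusted p, it takes the 2 members of smallest p that moved in the list's direction. Genes outside this rule are marked as chosen after their values were seen.

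Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights, RLE and upper-quartile factors, no filter on low counts, a mean of at least 1 CPM, a fit of the 2 groups compared, an absolute log2 fold change of at least 1, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were a correction for GC content and length, the 3 libraries Control 4, Model 2 and HBG 3 left out together, and genes that GENCODE M21 names as protein coding. GC content was computed from the GENCODE M21 transcripts, in which 52073 of the gene identifiers were found. It was known for 17488 of the tested genes (98.1%).

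The tests were checked on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. Counts were drawn from the mean of each gene over the 12 libraries, the library sizes and the fitted dispersions. Genes were drawn independently and libraries with equal quality, so the rates below need not hold for the measured libraries. In the simulation of Model against Control (17592 genes), 49 of the 2-fold and 90 of the 4-fold changes were recovered, with 8 false calls among 147. For HBG against Model (17586 genes), 47 and 81 were recovered, with 9 false calls among 137. For HBG against Control (17627 genes), 64 and 92 were recovered, with 6 false calls among 162. DESeq2 made 160 true calls among 217 in the simulation of Model against Control, 147 among 192 for HBG against Model and 169 among 221 for HBG against Control. In the same 3 simulations, limma-voom with sample quality weights made 139 true calls among 147, 123 among 127 and 152 among 156.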

Results

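Polyadenylated RNA of lung tissue was measured in 12 libraries, 4 in each of 3 groups of male C57BL/6 mice. Model mice received bleomycin, a drug used to produce lung fibrosis in mice, as 1 dose of 5 mg/kg into the trachea. HBG mice received the same dose and Huashibaidu granules, a Chinese herbal preparation, at 7 g/kg by mouth. The labels disagree on its timing. The description of the series has the granules start a week before bleomycin and continue to day 28, whereas the sample descriptions have them start on day 7 and last 14 days. The labels do not say that the 4 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Totals per library ranged from 18864850 to 27150874 estimated counts in Control, 19230871 to 22622450 in Model and 17979908 to 20752060 in HBG.

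The comparison of Model with Control asked which lung transcripts differed after bleomycin. Lists of extracellular matrix genes were higher in Model. All 14 tested fibrillar and other interstitial collagens had higher means, with a median of 1.51-fold (camera adjusted p = 4.38e-07, adjusted p = 0.533 with an estimated correlation). The 19 basement membrane genes were likewise all higher, by a median of 1.45-fold (camera adjusted p = 1.55e-09, adjusted p = 0.499 with an estimated correlation). Genes of monocyte-derived and scar-associated macrophages had a median of 1.83-fold, with 33 of 34 higher (camera adjusted p = 1.55e-09, adjusted p = 0.582 with an estimated correlation).

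No collagen passed the edgeR test over all genes, while 8 of the 14 passed when adjusted over the list alone. For the basement membrane list the counts were 0 over all genes and 11 adjusted over the list alone, and for the macrophage list 0 and 12. Type I collagen Col1a1 had 409 ± 159 CPM in Model and 247 ± 25.2 in Control (SD, n = 4 per group), a log2 fold change of 0.73 ± 0.26 (SE, edgeR adjusted p = 0.306). Col6a1 had 284 ± 41.9 and 188 ± 13.4 CPM, and Col4a1, a basement membrane collagen, 929 ± 203 and 498 ± 48.7 CPM. The laminin chain Lamc1 had 258 ± 17.7 CPM in Model and 177 ± 2.78 in Control (edgeR adjusted p = 0.0856). Among macrophage genes, Spp1 (osteopontin) had 731 ± 707 and 87.0 ± 42.6 CPM, and Cd68 51.9 ± 28.0 and 14.6 ± 1.47 CPM. The spread in Model was wide: Spp1 ranged from 108 to 1655 CPM across its 4 libraries, and its Model mean was 423 CPM without Model 1. Model 4 stood apart in list scores, the mean log2 CPM of the members relative to the mean library. Its macrophage score was -0.566, within the Control range of -0.571 to -0.41, against 0.28 to 1.19 in the other 3 Model libraries. Its collagen score was -0.103 and its basement membrane score -0.0513, against 0.316 to 0.849 and 0.267 to 0.415 in the other 3 and -0.305 to -0.125 and -0.363 to -0.212 in Control.

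Genes of matrix glycoproteins and proteoglycans had a median of 1.42-fold, with 27 of 28 higher (camera adjusted p = 6.64e-07, adjusted p = 0.499 with an estimated correlation). Of them, 10 passed when adjusted over the list alone and 0 over all genes. Fibronectin (Fn1, ENSMUSG00000026193), shared with the macrophage list, had 585 ± 286 CPM in Model and 186 ± 21.5 in Control (SD, n = 4 per group). Its log2 fold change was 1.66 ± 0.38 (SE), with all 4 Model libraries above all Control libraries (edgeR adjusted p = 0.119). Ltbp2, a latent TGF-beta binding protein, had 197 ± 85.2 and 109 ± 13 CPM. Matrix proteases and their inhibitors had a median of 1.56-fold (camera adjusted p = 9.91e-06, adjusted p = 0.499 with an estimated correlation), and 1 of the 23 members, Timp3, passed over all genes, with 4 passing when adjusted over the list alone. Timp3 (ENSMUSG00000020044), an inhibitor of metalloproteinases, rose from 667 ± 34.5 to 1040 ± 63.8 CPM, a log2 fold change of 0.64 ± 0.11 (SE, edgeR adjusted p = 0.0341), a call that was lost without each library but Model 4 (edgeR adjusted p up to 0.138). Ctss, a lysosomal protease, had 360 ± 216 and 95.1 ± 18.5 CPM. The matrix protease score of Model 4 was -0.217, within the Control range of -0.44 to -0.177, against 0.38 to 0.775 in the other 3 Model libraries.

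**Figure D1:**
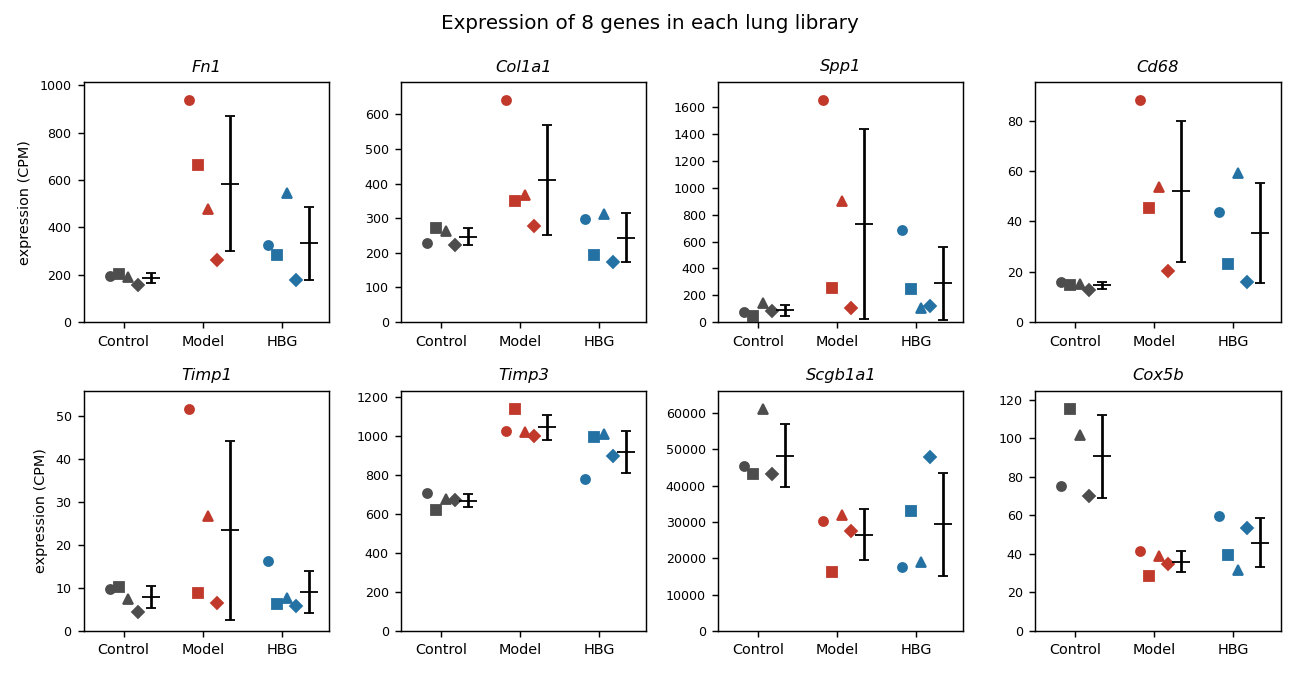
CPM of 8 genes (y axis, linear from 0) in each library of the 3 groups (x axis); marker shapes give the replicate number, and the bar beside each group is the mean ± SD (n = 4). Fn1 ranged from 263 to 938 CPM in Model and from 155 to 205 CPM in Control, and Timp3 from 997 to 1140 and from 621 to 704 CPM.

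Lists that were lower in Model held genes of other kinds. Immediate early and heat shock genes, which respond rapidly to stress, were lower, with a median fold change of 0.543 and 25 of 25 lower (camera adjusted p = 1.29e-05, adjusted p = 0.600 with an estimated correlation). None of these 25 passed the edgeR test over all genes and 1 passed when adjusted over the list alone. The Control scores were uneven, at 1.63 in Control 2, 0.638 in Control 3 and 0.00443 in Control 1. Control 4, at -0.346, lay within the Model range of -0.358 to -0.0444. Klf2, a transcription factor of endothelium, had 107 ± 18.4 CPM in Model and 244 ± 68.6 in Control, and the small heat shock protein Hspb1 49.6 ± 18.9 and 128 ± 53.1 CPM. Oxidative phosphorylation genes were lower, with a median fold change of 0.823 and 21 of 21 lower (camera adjusted p = 6.64e-07, adjusted p = 0.600 with an estimated correlation). Of these, 1 passed over all genes and 3 when adjusted over the list alone. Cox5b, a subunit of cytochrome c oxidase, fell from 90.6 ± 21.5 to 36.0 ± 5.54 CPM (edgeR adjusted p = 0.0294), a call lost without each library but Control 1 and Control 4 (edgeR adjusted p up to 0.106), and Uqcrfs1 had 46.9 ± 6.03 and 79.0 ± 15.2 CPM. Cardiac muscle genes were lower too, 19 of 19, with a median fold change of 0.423 (camera adjusted p = 5.4e-05, adjusted p = 0.716 with an estimated correlation), with no member passing on either scale. Their scores were -1.62 and -2.33 in Model 1 and Model 3. Model 2 and Model 4, at -0.0792 and 1.12, lay within the Control range of -0.876 to 2.01. The oxidative phosphorylation score was instead lowest in Model 2, at -0.414, and was 0.00135 in Model 1. Cox8b had 1.91 ± 1.79 and 8.23 ± 5.48 CPM, and the atrial myosin chain Myl4 97.3 ± 91.8 and 265 ± 180 CPM. Without Model 4 their Model means were 1.14 and 54.1 CPM. Cytosolic ribosomal protein genes were lower, with a median fold change of 0.936 and 21 of 26 lower (camera adjusted p = 0.000875, adjusted p = 0.756 with an estimated correlation). The call was lost without Model 4 (camera adjusted p = 0.205) and after a correction for GC content and length (camera adjusted p = 0.562). Of these genes, 1 passed over all genes and 2 adjusted over the list alone. The former was Rpl13, chosen after its values were seen, which fell from 391 ± 26.7 to 96.9 ± 21.3 CPM (edgeR adjusted p = 0.000133) and whose reads can be shared with near-identical copies. The other 3 lower lists were club and secretory epithelium, 16 of 19 lower (camera adjusted p = 0.0102, adjusted p = 0.756 with an estimated correlation), aryl hydrocarbon receptor and xenobiotic metabolism, 17 of 21 lower (0.00785 and 0.687), and erythrocytes, 8 of 10 lower (0.034 and 0.756). No member of these 3 passed over all genes or adjusted over the list alone. The club cell call was lost without Control 2, Model 1 or Model 3 (camera adjusted p up to 0.0848) and the aryl hydrocarbon receptor call without Model 1 (0.0655). The erythrocyte call was lost without Control 1, Control 4, Model 1, Model 3 or Model 4 (camera adjusted p up to 0.507) and after the GC and length correction (0.0622).

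Gene by gene, edgeR called 62 of 17827 genes, 9 higher and 53 lower in Model, with 2084 genes at an unadjusted p under 0.05. The groups did not overlap in 8.71% of the genes, where chance gives 2.86%. Left out by the naming rule and chosen after their values were seen were Gm38287, Iglv2 and Gm20458. Their log2 fold changes were 11.08, 3.895 and -5.484 (edgeR adjusted p = 0.000239, 0.00433 and 0.00529). Besides Timp3, P-selectin (Selp, ENSMUSG00000026580), an adhesion receptor of endothelium and platelets, rose from 3.81 ± 0.307 to 8.42 ± 1.41 CPM (edgeR adjusted p = 0.0195), and the lysosomal mannosidase Man2b2 from 44.5 ± 2.54 to 69.2 ± 7.75 CPM (edgeR adjusted p = 0.0416). The protease inhibitor Serpinb9b rose from 0.563 ± 0.216 to 2.53 ± 1.01 CPM (edgeR adjusted p = 0.042). Fam177a2 and Tmed2b had no counts in Control and 127 ± 8.11 and 18.1 ± 4.16 CPM in Model, at least 784-fold and at least 112-fold higher than the floor of 3 counts per library. Reads of Fam177a2 can be shared with Fam177a and those of Tmed2b with Tmed2, and the sum of Fam177a and Fam177a2 was 137 ± 7.26 CPM in Control and 135 ± 12.9 in Model. Scand1 (ENSMUSG00000046229) fell from 32.6 ± 6.11 to 1.33 ± 0.239 CPM, a log2 fold change of -4.61 ± 0.20 (SE, edgeR adjusted p = 3.44e-07). The zinc finger gene Zfp771 fell from 11.5 ± 1.22 to 1.69 ± 0.359 CPM, Tmem238 from 11.5 ± 1.32 to 2.15 ± 0.612, the histone gene H2ac18 from 14.3 ± 3.8 to 0.753 ± 0.623, the potassium channel gene Kcnk12 from 5.44 ± 0.786 to 1.02 ± 0.480 and neurturin (Nrtn) from 2.73 ± 0.762 to 0.350 ± 0.273 CPM. With 1 library left out, the calls of Serpinb9b, Man2b2 and Kcnk12 were lost without each library but Model 4, that of Nrtn without each but Model 3, that of Selp without each but Model 3 and Model 4, and that of H2ac18 without Control 1, Control 3 or Model 2 (edgeR adjusted p up to 0.153, 0.149, 0.17, 0.121, 0.106 and 0.0825 in that order). The 53 lower genes were GC-rich and short, with a median of 58.8% GC and 1275 bases, against 50.3% and 2696 bases over the genes tested. Scand1, Kcnk12 and Nrtn had 68.4%, 69.4% and 72.8% GC, and after a correction for GC content and length the 63 genes over 65% GC still had a median log2 fold change of -0.38, against -0.71 before. The calls of Kcnk12, Nrtn and Man2b2 were lost after it (edgeR adjusted p = 0.0999, 0.0728 and 0.0515), and the Model mean of Nrtn was 0.226 CPM without Model 3.

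Of the other key genes, the club cell secretoglobin Scgb1a1 had 26500 ± 7030 CPM in Model and 48200 ± 8650 in Control, and Timp1 had 23.4 ± 20.9 and 7.90 ± 2.59 CPM (edgeR adjusted p = 0.361 and 0.34). Col3a1 had 733 ± 295 CPM in Model and 431 ± 32.2 in Control, Tgfb1 61.6 ± 10.3 and 53.7 ± 8.26, Acta2 564 ± 261 and 577 ± 149, Postn 406 ± 45.1 and 364 ± 25.8, and Cthrc1 5.4 ± 3.65 and 4.19 ± 0.957 CPM. The epithelial genes Sftpc, Ager and Krt8 had 14700 ± 1920, 1960 ± 444 and 350 ± 46.7 CPM in Model and 15900 ± 2470, 1860 ± 383 and 289 ± 59.7 CPM in Control. Endothelial Pecam1 had 687 ± 279 and 557 ± 95.5 CPM, Il1b 21.4 ± 21 and 12.9 ± 5.75, Il6 1.35 ± 0.821 and 2.14 ± 3.06, Tnf 0.538 ± 0.284 and 1.54 ± 2.28, and Cdkn1a 543 ± 258 and 439 ± 260 CPM. The differences of the genes in this paragraph did not pass the edgeR test. The Model mean of Timp1 was 14 CPM without Model 1, and that of Il1b 11.1 CPM without Model 2. The Control means of Il6 and Tnf rested on Control 2, at 6.71 and 4.95 CPM (others 0.269 to 1.05 and 0.216 to 0.691). Without it their log2 fold changes were 1.076 and 0.40 in place of -0.66 and -1.51. The sign also turned for Acta2 without Control 2, Control 3, Model 1, Model 2 or Model 3 (log2 fold change up to 0.096) and for Ager without Control 2, Model 1 or Model 3 (down to -0.042). It turned for Cdkn1a without Control 4 (-0.075), Cthrc1 without Model 1 (-0.20) and Il1b without Model 2 (-0.21).

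Across the 60 lists, 21 were higher and 7 lower in Model by camera, and 0 changed with an estimated correlation or with fry, and other divisions of the same 8 libraries into 4 and 4 gave up to 39 lists. The gene count was 444 with DESeq2 (198 higher, 246 lower), 1079 with limma-voom and sample quality weights (620 higher, 459 lower), and 29, 35, 23, 36, 32, 28 and 39 without Control 1, Control 2, Control 3, Control 4, Model 1, Model 2 and Model 3, while without Model 4 it was 67, of which 33 were higher and 34 lower.

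**Figure D2:**
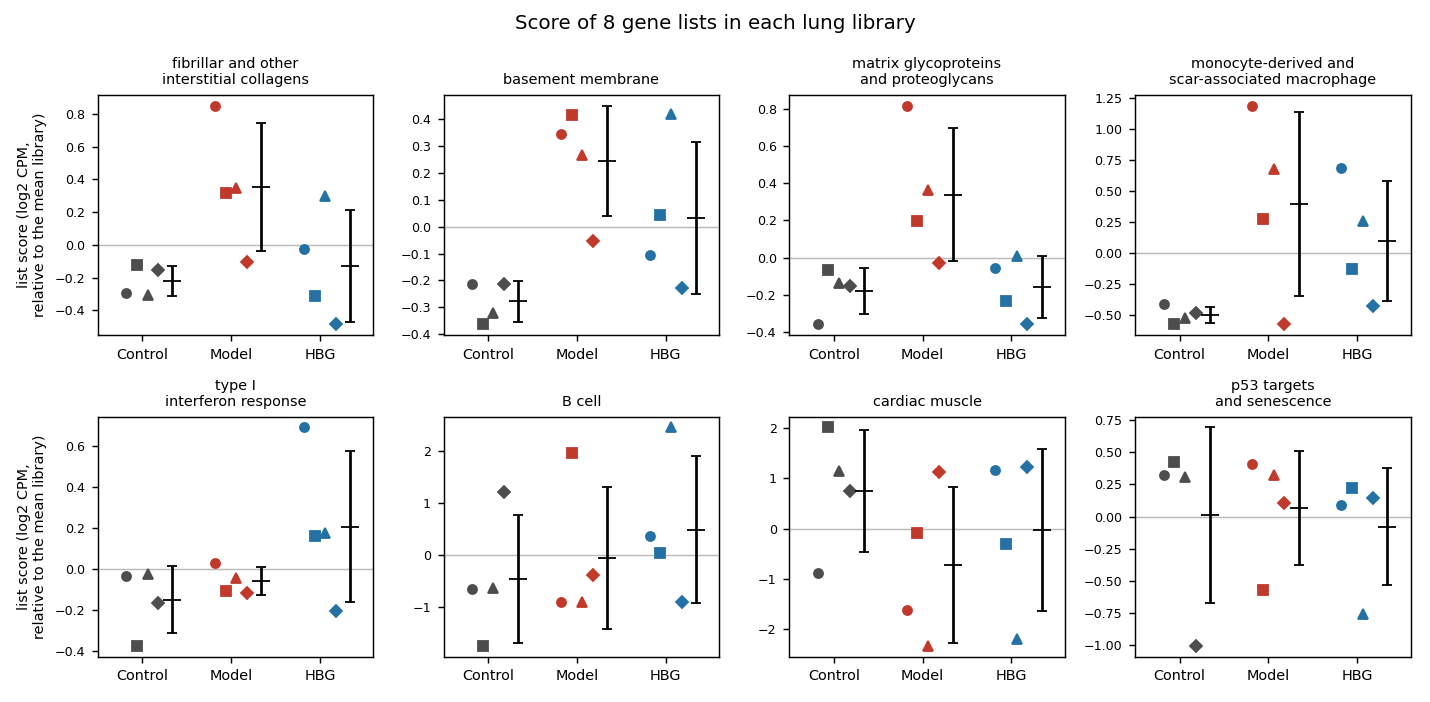
Score of 8 gene lists (y axis, mean log2 CPM of the members relative to the mean library) in each library of the 3 groups (x axis); marker shapes give the replicate number, and the bar beside each group is the mean ± SD (n = 4). Mean collagen scores were -0.220 in Control, 0.351 in Model and -0.132 in HBG, and mean type I interferon scores -0.149, -0.0583 and 0.207.

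The comparison of HBG with Model asked which transcripts differed when granules were added to bleomycin. Matrix lists were lower in HBG. Matrix glycoproteins and proteoglycans were lower, with a median fold change of 0.720 and 27 of 28 lower (camera adjusted p = 1.11e-13, adjusted p = 0.193 with an estimated correlation). Collagen processing and crosslinking genes were lower, with a median fold change of 0.830 and 20 of 22 lower (camera adjusted p = 4.81e-11, adjusted p = 0.193 with an estimated correlation), and fibrillar and other interstitial collagens were lower with a median fold change of 0.702 and 14 of 14 lower (camera adjusted p = 2.55e-10, adjusted p = 0.437 with an estimated correlation). Genes of myofibroblasts and activated fibroblasts were lower, with a median fold change of 0.817 and 16 of 17 lower (camera adjusted p = 8.36e-06, adjusted p = 0.193 with an estimated correlation). Scores of single libraries overlapped for some of these lists. The collagen score was 0.297 in HBG 3 (other HBG libraries -0.485 to -0.0264) and -0.103 in Model 4 (other Model libraries 0.316 to 0.849). The myofibroblast score was 0.253 in HBG 1, and 0.0564 and 0.0118 in Model 2 and Model 4. Scores of collagen processing and crosslinking did not overlap (-0.21 to -0.0351 in HBG, 0.0309 to 0.4 in Model). Type I interferon response genes were higher by a median of 1.25-fold, with 27 of 28 higher (camera adjusted p = 1.78e-10, adjusted p = 0.437 with an estimated correlation). Their score was 0.69 in HBG 1, 0.164 in HBG 2 and 0.175 in HBG 3. HBG 4, at -0.202, lay below the Model range of -0.115 to 0.0314.

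No member of these lists passed the edgeR test over all genes, and 0 passed when adjusted over the list alone. Mfap5, a microfibril protein, had 31.8 ± 4.36 CPM in HBG and 52.1 ± 16.4 in Model (SD, n = 4 per group), with the 4 HBG libraries below the 4 Model libraries. Over all genes tested, HBG and Model did not overlap in 1.13%, where chance gives 2.86%. The proteoglycan Vcan had 14.6 ± 3.04 and 22.5 ± 5.10 CPM, the collagen crosslinking enzyme Loxl2 42.3 ± 6.20 and 63.8 ± 14.4, and Fkbp10, a collagen chaperone, 26.1 ± 1.35 and 33.9 ± 5.34 CPM. Col1a1 had 244 ± 70.5 and 409 ± 159 CPM, a log2 fold change of -0.75 ± 0.26 (SE), Col5a2 93.2 ± 23.4 and 157 ± 72.6, Ltbp2 119 ± 17.4 and 197 ± 85.2, and tenascin C (Tnc) 31.6 ± 17.5 and 76.5 ± 50.4 CPM. Of the interferon-induced genes, Ifi27l2a had 88.3 ± 18.2 CPM in HBG and 55.9 ± 9.87 in Model, and Irf7 66.4 ± 27.7 and 41.0 ± 6.83 CPM.

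Lists of other tissues, cell types and RNA quality moved in the same comparison. Cytosolic ribosomal protein genes were higher by a median of 1.07-fold, with 21 of 26 higher (camera adjusted p = 5.38e-05, adjusted p = 0.833 with an estimated correlation). This call was lost without Model 4 (camera adjusted p = 0.365). Cardiac muscle genes were higher by 1.56-fold, with 18 of 19 higher (camera adjusted p = 0.00167, adjusted p = 0.879 with an estimated correlation). Their call was lost without HBG 1, HBG 4, Model 1 or Model 3 (camera adjusted p up to 0.455). Oxidative phosphorylation genes were higher by 1.09-fold, with 16 of 21 higher (camera adjusted p = 0.00288, adjusted p = 0.879 with an estimated correlation). The call was lost without HBG 1, HBG 4 or Model 2 (camera adjusted p up to 0.349). Mitochondrially encoded genes were lower, with a median fold change of 0.783 and 11 of 13 lower (camera adjusted p = 0.000702, adjusted p = 0.833 with an estimated correlation). This was lost without HBG 3 or Model 4 (camera adjusted p up to 0.305). Type 1 alveolar epithelium genes were lower, with a median fold change of 0.898 and 17 of 19 lower (camera adjusted p = 0.00167, adjusted p = 0.833 with an estimated correlation). It was not called without HBG 1 or Model 3 (camera adjusted p up to 0.309). Monocyte-derived and scar-associated macrophage genes were lower, with a median fold change of 0.805 and 26 of 34 lower (camera adjusted p = 0.0114, adjusted p = 0.879 with an estimated correlation). This list was not called without HBG 2, HBG 4 or Model 3 (camera adjusted p up to 0.541). Without Model 1 its direction turned (camera adjusted p = 0.929). No member of these 6 lists passed over all genes, and adjusted over the list alone 1 of the ribosomal list and 0 of the others passed.

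Lists of lymphocytes were also higher in HBG: NK and cytotoxic cells by a median of 1.47-fold with 17 of 17 higher (camera adjusted p = 2.35e-07, adjusted p = 0.833 with an estimated correlation), and T cells by 1.28-fold with 26 of 28 higher (camera adjusted p = 9.54e-06, adjusted p = 0.833 with an estimated correlation). Interferon-gamma response and antigen presentation genes were higher by 1.21-fold, with 29 of 31 higher (camera adjusted p = 2.82e-07, adjusted p = 0.833 with an estimated correlation). None of their members passed over all genes or adjusted over the list alone. The NK receptor genes Klra4 and Klra8 had 3.47 ± 1.88 and 5.03 ± 2.07 CPM in HBG and 1.65 ± 1.97 and 2.87 ± 3.08 in Model, where the means were 0.698 and 1.39 CPM without Model 2. The transcription factor Tbx21 had 3.01 ± 2.06 and 1.22 ± 0.702 CPM, the T cell receptor gene Trbc1 5.91 ± 1.72 and 3.69 ± 2.54 (Model 2 at 7.47, the other Model libraries at 2.03 to 2.81), Igtp 38.7 ± 10.4 and 28.0 ± 3.57, and the peptide transporter Tap1 83.2 ± 8.95 and 68.2 ± 7.43 CPM. HBG 3 stood apart in lymphocyte lists, with a B cell score of 2.46, and without it the camera adjusted p was 0.252 for T cells and 0.0903 for the interferon-gamma list. Model 2 stood apart in the same lists, with a B cell score of 1.96, a T cell score of 1.31 and an NK and cytotoxic cell score of 1.55, against at most -0.368, -0.429 and -0.187 in the other Model libraries. Without it the T cell and NK lists were called (camera adjusted p = 1.55e-14 and 2.37e-17).

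Of the remaining key genes, Fn1 had 333 ± 154 CPM in HBG and 585 ± 286 in Model, Spp1 290 ± 273 and 731 ± 707, Timp1 8.98 ± 4.90 and 23.4 ± 20.9, Col3a1 465 ± 192 and 733 ± 295, and Tgfb1 51.0 ± 17.4 and 61.6 ± 10.3 CPM. For Acta2 the HBG level was 486 ± 234 CPM, for Postn 369 ± 141, for Cthrc1 3.70 ± 0.635, for Sftpc 12500 ± 3360, for Ager 1810 ± 251, for Scgb1a1 29300 ± 14100, for Pecam1 617 ± 290, for Krt8 363 ± 209, for Cdkn1a 409 ± 227, for Il1b 13.2 ± 8.15, for Il6 0.833 ± 0.353 and for Tnf 0.693 ± 0.408 CPM. None of these differences from Model passed the edgeR test. The HBG mean of Spp1 was 157 CPM without HBG 1 and its Model mean 423 CPM without Model 1. The Model means of Timp1 and Il1b were 14 CPM without Model 1 and 11.1 CPM without Model 2. With 1 library left out, the sign turned for Acta2 without HBG 3 or Model 4 (log2 fold change up to 0.16), Ager without Model 3 (0.0016), Cthrc1 without Model 1 (0.013) and Il1b without Model 2 (0.25). It also turned for Krt8 without HBG 1, HBG 4 or Model 2 (down to -0.34), Pecam1 without HBG 1 or Model 2 (up to 0.12), Postn without HBG 1 (0.091) and Scgb1a1 without HBG 4 or Model 2 (down to -0.20).

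Over all genes, edgeR called 0 of 17827 between HBG and Model, with 433 at an unadjusted p under 0.05 where chance gives 891, and a smallest edgeR adjusted p of 0.9999. limma-voom with sample quality weights called 0, with 2632 at an unadjusted p under 0.05, and DESeq2 called 4, chosen here after their values were seen: Fblim1, H2ac18, Gm5559 and the unnamed gene ENSMUSG00000120425. By camera, 9 lists were higher and 17 lower in HBG, 0 with an estimated correlation or with fry, and other divisions of the 8 libraries gave up to 38 lists.

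Whether genes moved by bleomycin moved back in HBG was examined in both comparisons together. No gene passed the edgeR threshold in Model against Control and, with the opposite sign, in HBG against Model, while DESeq2 gave 3. Of the 62 genes called in Model, 54 had the opposite sign in HBG against Model. Over all 62, the median log2 fold change in HBG against Model was 0.187 towards Control, beside a median size of 1.24 in Model against Control. Both comparisons use the Model libraries, which by itself gives fold changes of opposite sign. Across 15872 genes, which are not independent replicates, their correlation was -0.380, against -0.498 in 20 simulations of unchanged groups. The covariance was -0.0390 against a simulated -0.0460, and opposite signs were seen for 65.3% of the genes against a simulated 66.7%. With different Model libraries in each comparison, the correlation averaged 0.0402 over 6 assignments and ranged from -0.291 to 0.234.

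The comparison of HBG with Control asked what differed from Control when both bleomycin and granules were given. Several immune lists were higher in HBG. Those of neutrophils, alveolar macrophages, proinflammatory cytokines and chemokines, NF-kB targets, and mast cells, basophils and eosinophils were not called by camera. Genes of the interferon-gamma response and antigen presentation were higher by a median of 1.37-fold, with 28 of 31 higher (camera adjusted p = 5.12e-08, adjusted p = 0.876 with an estimated correlation), and type I interferon response genes by 1.30-fold with 26 of 28 higher (camera adjusted p = 1.7e-07, adjusted p = 0.876 with an estimated correlation). Monocyte-derived and scar-associated macrophage genes were higher by 1.63-fold, with 32 of 34 higher (camera adjusted p = 9.05e-07, adjusted p = 0.877 with an estimated correlation). Plasma cell genes were higher by 2.50-fold, with 18 of 20 higher (camera adjusted p = 5.38e-06, adjusted p = 0.876 with an estimated correlation), and T cell genes by 1.87-fold with 27 of 28 higher (camera adjusted p = 3.04e-06, adjusted p = 0.920 with an estimated correlation). HBG 4 scored within the Control range in each of these called lists. Its macrophage score was -0.426 (Control -0.571 to -0.41) and its plasma cell score -0.573 (-1.1 to -0.192). Its T cell score was -0.35 (-1.34 to 0.321), its type I interferon score -0.202 (-0.373 to -0.0238) and its interferon-gamma score -0.233 (-0.527 to 0.124). For T cells, HBG 1 (0.263) also lay within the Control range, with HBG 2 at 0.342 and HBG 3 at 1.43. The low end of that range was Control 2, with the other Control libraries at -0.163 to 0.321.

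No member of the 5 higher lists given above passed the edgeR test over all genes. Adjusted over the list alone, 4 of the interferon-gamma list, 1 of the type I interferon list, 10 of the plasma cell list and 0 of the macrophage and T cell lists passed. The chemokine Cxcl9 had 3.58 ± 3.49 CPM in HBG and 0.468 ± 0.0640 in Control (SD, n = 4 per group), with HBG 1 at 8.72 and an HBG mean of 1.86 CPM without it, and B2m 1420 ± 343 and 857 ± 142 CPM. Irf7 had 66.4 ± 27.7 CPM in HBG and 32.1 ± 3.30 in Control, and the RNA sensor Ifih1 54.1 ± 11.1 and 40.5 ± 1.76 CPM. Macrophage elastase Mmp12 had 40.8 ± 61.8 and 3.85 ± 1.5 CPM, with HBG 1 at 133 CPM and the other HBG libraries at 6.77 to 12.6, and Adgre1 (F4/80) 23.9 ± 10.2 and 10.1 ± 1.31. The immunoglobulin constant genes Ighg2b and Ighg2c had 45.6 ± 59.6 and 80.6 ± 125 CPM in HBG, with HBG 1 at 134 and 268 CPM, and 3.67 ± 1.66 and 4.82 ± 1.34 CPM in Control. Zap70 had 9.28 ± 2.10 and 6.79 ± 1.45 CPM, and Cd4 10.4 ± 5.70 and 5.05 ± 1.30 CPM.

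Basement membrane genes were higher in HBG by a median of 1.22-fold, with 18 of 19 higher (camera adjusted p = 3.69e-05, adjusted p = 0.876 with an estimated correlation), and fibrillar and other interstitial collagens had a median of 1.06-fold (camera adjusted p = 0.286). Lama3 had 138 ± 66.1 CPM in HBG and 72.5 ± 13.2 in Control, and Col4a3 222 ± 97.4 and 126 ± 32.8 CPM. Immediate early and heat shock genes were lower, with a median fold change of 0.522 and 25 of 25 lower (camera adjusted p = 9.05e-07, adjusted p = 0.876 with an estimated correlation), where 0 passed over all genes and 2 adjusted over the list alone. Klf2 had 125 ± 31.9 CPM in HBG and 244 ± 68.6 in Control, and Hspb1 45.5 ± 18.2 and 128 ± 53.1 CPM. The scores of this list were 1.63 and 0.638 in Control 2 and Control 3. Control 1 and Control 4, at 0.00443 and -0.346, lay within the HBG range of -0.472 to 0.181. Mitochondrially encoded genes were lower, with a median fold change of 0.666 and 13 of 13 lower (camera adjusted p = 4.79e-06, adjusted p = 0.876 with an estimated correlation), with 0 passing over all genes and 1 adjusted over the list alone. Their score was -0.473 in HBG 2 and -1.01 in HBG 3. HBG 1 and HBG 4, at 0.0658 and 0.0775, lay within the Control range of 0.0615 to 0.63. For mt-Atp8 the levels were 314 ± 27.2 CPM in HBG and 772 ± 330 in Control, and for mt-Nd4l 32.1 ± 14.3 and 65.9 ± 24.2 CPM. Oxidative phosphorylation genes were also lower, 21 of 21, with a median fold change of 0.897 (camera adjusted p = 0.000844, adjusted p = 0.920 with an estimated correlation). Of these, 0 passed over all genes and 1 adjusted over the list alone. The call was lost without Control 2 or HBG 3 (camera adjusted p up to 0.143). Cardiac muscle genes were likewise lower, 19 of 19, with a median fold change of 0.669 (camera adjusted p = 0.036, adjusted p = 0.920 with an estimated correlation). No member passed over all genes or adjusted over the list alone. That call was lost without Control 2, Control 3, Control 4, HBG 2 or HBG 3 (camera adjusted p up to 0.84).

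Gene by gene, edgeR called 27 genes, 4 higher and 23 lower in HBG, with 1470 at an unadjusted p under 0.05. Gm38287, Iglv2 and Gm20458, again outside the naming rule, had log2 fold changes of 11.14, 3.35 and -6.911 (edgeR adjusted p = 0.000316, 0.016 and 0.00312). Cebpb, a transcription factor of inflammatory and myeloid cells, fell from 101 ± 31.2 CPM in Control to 17.6 ± 4.66 in HBG (edgeR adjusted p = 0.00248), and Jund, a subunit of the AP-1 transcription factor, from 307 ± 76.2 to 76.9 ± 20.7 CPM (edgeR adjusted p = 0.00249). Scand1 fell to 1.73 ± 0.298 CPM, Zfp771 to 2.04 ± 0.540, Tmem238 to 2.17 ± 0.567 CPM, and Kcnk12 was 6.56-fold lower (edgeR adjusted p = 0.0486), a call lost without each library but HBG 3 (edgeR adjusted p up to 0.14). Fam177a2 and Tmed2b had 114 ± 14.8 and 14.1 ± 2.34 CPM in HBG, at least 707-fold and at least 86.9-fold above the Control floor, with reads that can be shared with their copies. The 23 lower genes had a median GC content of 59.9%. Cebpb, Jund, Scand1 and Kcnk12 had 67.2%, 67.1%, 68.4% and 69.4% GC, and after the correction for GC content and length the 63 genes over 65% GC still had a median log2 fold change of -0.34, against -0.73 before. The call of Kcnk12 was lost after it (edgeR adjusted p = 0.0835).

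Of the genes called in both comparisons with Control, 25 changed in the same direction, 4 higher and 21 lower. Independent lists would share 0.00202 and 0.0684, but the lists are not independent, since both comparisons use the Control libraries. Simulated unchanged groups shared 0, which says little, since few genes can be called where none was changed. Across genes, the fold changes of both comparisons had a correlation of 0.836 (0.501 simulated) and a covariance of 0.145 (0.0464 simulated), a difference in covariance of 0.0985. With different Control libraries in each comparison, the correlation ranged from 0.483 to 0.691 and 11 to 14 genes were called in both.

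By camera, 16 lists were higher and 8 lower in HBG than in Control, 0 with an estimated correlation or with fry, 14 lists without HBG 3, and up to 35 in other divisions of the 8 libraries. The gene count was 205 with DESeq2 (49 higher, 156 lower), 101 with limma-voom and sample quality weights (9 higher, 92 lower), and 17, 16 and 17 without Control 1, Control 3 and HBG 2.

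**Figure D3:**
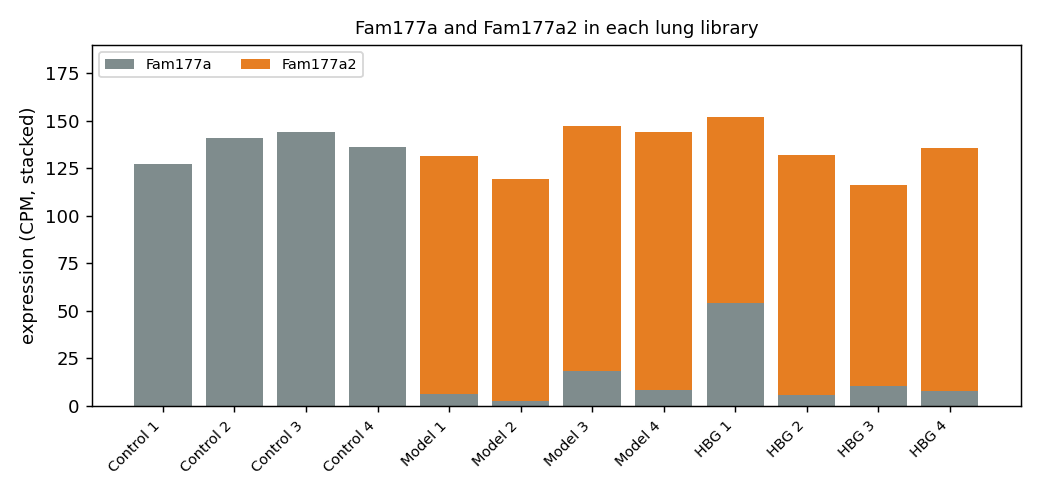
CPM of Fam177a and Fam177a2, stacked (y axis, linear from 0), in each of the 12 libraries (x axis). Fam177a2 was at 0 in the 4 Control libraries and at 97.6 to 136 CPM in the others, while the sum of both genes ranged from 117 to 152 CPM.

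**Figure D4:**
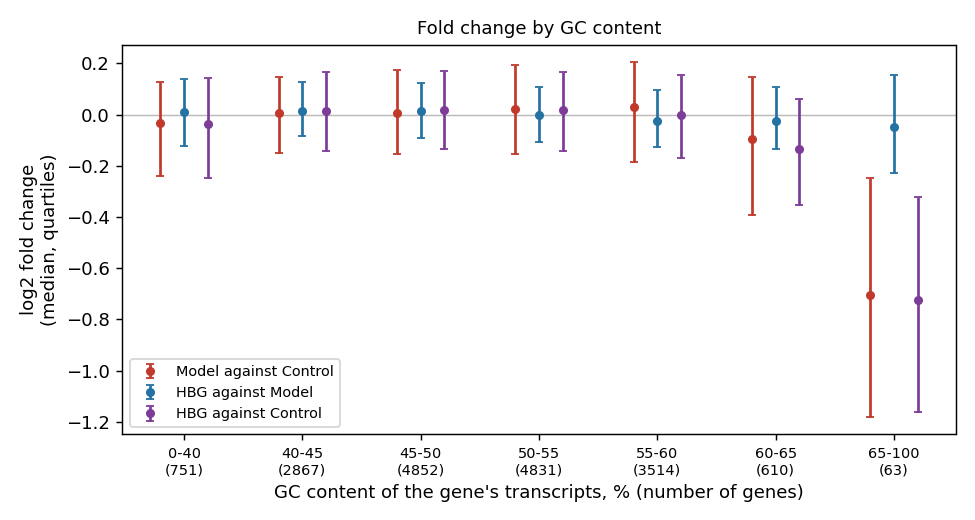
Median log2 fold change (points) with quartiles (bars) of the tested genes by GC content in percent (x axis, number of genes in brackets), for the 3 comparisons. The 63 genes over 65% GC had medians of -0.706 in Model against Control, -0.725 in HBG against Control and -0.0491 in HBG against Model.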

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

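Each library was compared with the other 3 of its group, for the named genes, the called lists and the totals, and is listed where it lay far from the others. Of 298 groups examined, 22 had such a library, where chance gives about 1 in 20, or 15. No explanation was tested for these values, and none of them is a difference between groups.

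In Control 2, Tnf was at 4.95 CPM (others 0.216 to 0.691), Il6 at 6.71 (0.269 to 1.05), Krt8 at 378 (258 to 260) and Kcnk12 at 6.61 CPM (4.90 to 5.17). The same library had a score of 0.448 for proinflammatory cytokines and chemokines (-0.432 to -0.400) and -1.22 for NK and cytotoxic cells (0.203 to 0.347). Scgb1a1 was at 61100 CPM in Control 3 (43200 to 45300), and the score for NRF2 and glutathione was -0.177 in Control 4 (0.161 to 0.209).

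In Model 2, Timp3 was at 1140 CPM (others 997 to 1020), Tnf at 0.959 (0.362 to 0.457) and Trbc1 at 7.47 CPM (2.03 to 2.81), and the T cell score was 1.31 (-0.751 to -0.429). Model 4 had 953 CPM of Acta2 (408 to 481) and a smooth muscle score of 0.658 (-0.302 to -0.162). The total of Model 3 was 22.6 M counts, M being the prefix mega (others 19.2 to 19.8 M).

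In HBG 1, Mmp12 was at 133 CPM (others 6.77 to 12.6), Irf7 at 108 (48.2 to 55.7), Ighg2b at 134 (6.88 to 28.4) and Ighg2c at 268 CPM (7.54 to 36.4). HBG 3 had 24.1 CPM of Fkbp10 (26.5 to 26.9) and an erythrocyte score of 1.32 (-0.683 to -0.523). In HBG 4, Tap1 was at 69.9 CPM (86.9 to 89.0).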

How the results depend on the processing

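The correction for GC content and length, the 3 libraries Control 4, Model 2 and HBG 3 left out together, and the genes named as protein coding were chosen after seeing the data; the other settings were fixed before. The count of genes in Model against Control, 62 with edgeR, was 444 with DESeq2, 1079 with limma-voom and sample quality weights, 40 with an absolute log2 fold change of at least 1, and 23 (without Control 3) to 67 (without Model 4, 33 higher and 34 lower) with 1 library left out. All 62 genes were also called by DESeq2 and by limma-voom. It was 59 after the correction for GC content and length (50 shared), 46 without the 3 libraries (39 shared) and 54 among protein coding genes. The count in HBG against Control, 27, was 205 with DESeq2, 101 with limma-voom and 16 (without Control 3) to 25 (without HBG 3) with 1 library left out. In HBG against Model it was 0 in each setting except DESeq2, which gave 4, and the count of genes changed in Model and the opposite way in HBG was 0 except with DESeq2, which gave 3. The count of lists was 0 with an estimated correlation and 0 with fry in each comparison, and with 1 library left out it was 24 to 35 in Model against Control, 19 to 32 in HBG against Model and 14 to 28 in HBG against Control. The cause of these differences was not tested. Fits with libraries left out also have fewer samples, and that was not tested as a cause either. On simulated counts of Model against Control, 160 of 217 calls of DESeq2 and 139 of 147 calls of limma-voom were true. The simulated libraries had equal quality, whereas the quality weights of the measured ones ranged from 0.231 (HBG 3) to 2.96 (Model 3). These shares therefore need not hold for the measured counts.

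Same-numbered libraries did not deviate together: of 12 pairs the correlations of deviations ranged from -0.357 to 0.481, with 3 over 0.1, and in 5 of 24 tests a library matched its own number best. With the replicate number as a block, 25 genes were called in Model against Control and 17 in HBG against Control, 0 in HBG against Model, and 30, 28 and 24 lists in the 3 comparisons.

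Of the 21 called values of named genes, 12 kept direction and call under each alternative tried, among them Scand1, Zfp771, Tmem238, Fam177a2 and Tmed2b in both comparisons with Control, and Cebpb and Jund in HBG against Control. Scand1, Cebpb and Jund are over 65% GC, where the correction left 53.6% of the trend in Model against Control. In HBG against Control the median log2 fold change of genes over 65% GC was -0.725 before the correction and -0.338 after it. With 1 library left out, the edgeR adjusted p in Model against Control reached 0.138 for Timp3, 0.106 for Selp, 0.153 for Serpinb9b, 0.149 for Man2b2, 0.106 for Cox5b, 0.121 for Nrtn, 0.170 for Kcnk12 and 0.0825 for H2ac18. Without the 3 libraries the calls of Timp3, Selp, Serpinb9b, Man2b2, Nrtn and H2ac18 in Model against Control were lost (0.133, 0.143, 0.228, 0.176, 0.136 and 0.0831), as was that of Kcnk12 in HBG against Control (0.0585). Of the named genes that edgeR did not call, DESeq2 called 20 values and limma-voom 14. Of 78 list calls, 36 held with each library left out in turn.

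The signs of uncalled genes turned in some settings (log2 fold changes; the cause was not tested). With limma-voom these were Acta2 at 0.030, Krt8 at -0.079 and Pecam1 at 0.12 in HBG against Model, Pecam1 at -0.11 and Il6 at 0.62 in Model against Control, and in HBG against Control Ager at 0.0069, Cdkn1a at 0.33, Col3a1 at -0.28, Il1b at -0.26, Postn at -0.020 and Timp1 at -0.16. Without the 3 libraries, Acta2 was at 0.10 and Il1b at -0.31 in Model against Control, and Col3a1 at -0.21, Il1b at -0.56, Pecam1 at -0.091 and Postn at -0.15 in HBG against Control, where the lists of ciliated epithelium and smooth muscle also turned (adjusted p = 0.0962 and 0.749 by camera). After the correction for GC content and length, Sftpc was at 0.068 in Model against Control, and Ager at 0.18 and Cdkn1a at 0.017 in HBG against Control. Col1a1 was at 0.014 without a filter and Postn at -0.0069 among protein coding genes in HBG against Control. With the replicate block, Il1b was at -0.071 and Postn at -0.058 in HBG against Control, and Krt8 at -0.066 in HBG against Model. With different Model libraries in each comparison, the correlation of fold changes was 0.234, 0.173, 0.131 and 0.195 in 4 of 6 assignments.

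With 1 library left out, the log2 fold change in Model against Control ranged from -0.41 to 0.10 for Acta2, -0.042 to 0.20 for Ager, -0.075 to 0.60 for Cdkn1a, -0.20 to 0.58 for Cthrc1, -0.21 to 1.05 for Il1b, -1.04 to 1.076 for Il6 and -1.94 to 0.40 for Tnf. In HBG against Model it ranged from -0.54 to 0.16 for Acta2, -0.21 to 0.0016 for Ager, -0.76 to 0.013 for Cthrc1, -1.21 to 0.25 for Il1b, -0.34 to 0.31 for Krt8, -0.46 to 0.12 for Pecam1, -0.33 to 0.091 for Postn and -0.20 to 0.33 for Scgb1a1. In HBG against Control it ranged from -0.14 to 0.084 for Ager, -0.49 to 0.25 for Cdkn1a, -0.16 to 0.11 for Col1a1, -0.19 to 0.26 for Col3a1, -0.48 to 0.29 for Il1b, -1.73 to 0.38 for Il6, -0.060 to 0.59 for Krt8, -0.16 to 0.40 for Pecam1, -0.17 to 0.25 for Postn, -0.33 to 0.056 for Tgfb1, -0.27 to 0.35 for Timp1 and -1.50 to 0.77 for Tnf. The adjusted p by camera ranged from 5.74e-08 to 0.617 for B cells, 0.000468 to 0.872 for adipocytes and 4.55e-09 to 0.929 for monocyte-derived and scar-associated macrophages in HBG against Model, and from 2.24e-05 to 0.237 for ciliated epithelium in HBG against Control. Planned settings on a biotype column and on a pseudocount were not run: the table gives no biotype, and a pseudocount does not apply to counts.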

Other observations

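The tests of GC content and length, of the extent of injury, of shared reads, of a variant and of the library Model 1, the splits that count genes or lists in each comparison, and those of the matrix lists in Model against Control, were chosen after the results were seen; the other tests were set out before.

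Alveolar epithelium lists were higher in Model than in Control by camera. Type I alveolar genes had a median of 1.27-fold with 17 of 19 higher (camera adjusted p = 0.000387, adjusted p = 0.600 with an estimated correlation), and genes of transitional alveolar epithelium, a state between the alveolar cell types, 1.37-fold with 18 of 19 higher (camera adjusted p = 9.56e-05, adjusted p = 0.600 with an estimated correlation). Type II alveolar and surfactant genes had 1.14-fold with 20 of 22 higher (camera adjusted p = 0.0102, adjusted p = 0.756 with an estimated correlation). Their call was lost without Control 4 or Model 1 (camera adjusted p up to 0.329) and without Control 4, Model 2 and HBG 3 together (0.061). Plasma cell genes were higher by 1.93-fold with 17 of 20 higher (camera adjusted p = 0.00303, adjusted p = 0.687 with an estimated correlation). No member of these 4 lists passed over all genes, and adjusted over the list alone 3 of the transitional list and 0 of the others passed. The type I score was 0.258 in Model 1 and 0.484 in Model 3. Model 2 and Model 4 (-0.00126 and -0.118) lay within the Control range of -0.393 to 0.147. Their transitional scores (-0.00664 and -0.152) also lay within Control (-0.552 to 0.00338), against 0.773 and 0.694 in Model 1 and Model 3. For type II genes, Model 1 alone (0.438) was above Control (-0.176 to 0.136). The plasma cell score of Model 4 (-0.419) lay within Control (-1.1 to -0.192).

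The score of p53 targets and senescence was -1.01 in Control 4, -0.573 in Model 2 and -0.761 in HBG 3, and 0.0886 to 0.426 in the other 9 libraries. Cdkn1a, a p53 target that halts the cell cycle, was at 55.4, 174 and 73.5 CPM in these 3 libraries, in the same order, and at 477 to 751 CPM in the other 9 libraries. The clock gene Per2, chosen after its values were seen, was at 41.3, 51.2 and 31.7 CPM in them and at 91.1 to 121 CPM in the other 9. Their B cell scores were 1.22, 1.96 and 2.46, and their cell cycle scores 0.606, 0.932 and 1.52. These libraries were not compared as a group, and no explanation was tested.

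Genes lower in both bleomycin groups were GC-rich and short: 63 genes over 65% GC had median log2 fold changes of -0.71 in Model and -0.73 in HBG against Control. When a trend with GC content and length was removed, 39 of the 47 lower genes of at most 65% GC, 1 of them with no known GC content, stayed called (median log2 fold change -1.16 before, -0.98 after), which argues against that trend as their whole cause, while of the 6 lower genes over 65% GC, Scand1, Cebpb and Jund among the 6, 3 stayed called (-2.40 and -1.96) and they cannot be told apart from it, since 53.6% of the trend was left. A response that scales with the extent of injury, as the macrophage score measures it, was tested in the 4 HBG libraries. The 58 genes used were called lower from the Control and Model libraries alone. Drawn out to the Control score they gave 3.54 (log2 CPM, 3.20 to 3.74 with 1 HBG library left out). That lies near the HBG mean of 3.46 and not the Control mean of 4.74. This cannot decide the question, since the call favours genes with a small spread within Model. Macrophage scores there ranged from -0.566 to 1.19, so genes that follow the score were less likely to be chosen. A difference in handling between the Control libraries and the others was not tested, because no label gives a batch. A response to bleomycin that does not follow the macrophage score was not tested, and both kinds of response stay open.

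Fam177a2 was at 0 in the 4 Control libraries, as were Tmed2b and Gm38287, the latter chosen after its values were seen. Gm20458, Rpl13 and Rnaset2a, also chosen so, went the other way, from 5.91 to 7.95, 361 to 422 and 65 to 81.4 CPM in Control to 0 to 0.254, 69.8 to 186 and 13.4 to 31.9 CPM in the 8 bleomycin libraries. Rnaset2b, chosen likewise, did not rise where Rnaset2a fell, at 125 to 153 CPM in Control and 118 to 145 CPM in the bleomycin libraries. The sum of Fam177a and Fam177a2 differed between Model and Control by a log2 fold change of -0.0167 ± 0.0989 (SE), so a division of the same reads between both genes may account for the difference, as a hypothesis. A variant carried by the mice of one group would put the share of Fam177a2 in the sum near 0%, 50% or 100%, but 2 of the 8 bleomycin libraries lay over 10 points from these, with shares from 64.3% to 98% over the 8, and without genotypes the variant cannot be told apart from a difference in counting. No biological explanation was tested.

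The 7 lists of matrix and TGF-beta genes were higher in Model than in Control and lower in HBG than in Model by camera (adjusted p from 1.55e-09 to 0.00333 and from 1.11e-13 to 0.000224, and with an estimated correlation from 0.499 to 0.6 and from 0.193 to 0.746). Without Model 1, the library with the highest Fn1 and Spp1, 7 of the 7 stayed called in both comparisons, which argues against that library as the cause. With different Model libraries in each comparison, 6 of 6 assignments had the 7 lists higher and then lower, with 5 to 7 called both ways, which argues against the shared libraries as the cause. However, 4 of the 35 splits of the Model and HBG libraries and 4 of the 35 splits of the Control and Model libraries called 7 of these lists in one direction (real value 7 and highest other 7 in both), so the spread between libraries within a group may account for either part of the pattern. An effect of the granules on matrix genes stays open as a hypothesis.

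In Model against Control, 1 of the 35 splits of the 8 libraries, the real one, gave as many genes (62, highest other 1). The same held in HBG against Control (1 of 35, with 27 genes and highest other 0). Chance is thus unlikely for these gene counts. It is not excluded, since 1 of 35 is the fewest that these splits can give. The splits also cannot tell an effect of bleomycin from a difference in handling of the Control libraries. In HBG against Model the real count was 0, which each of the 35 splits reaches by construction (35 of 35), so the splits say nothing about chance there. Among them, Model 1, Model 3, HBG 1 and HBG 4 against the rest gave 561 genes, which may point to a structure of the samples other than the groups. That was not tested, and HBG 4 correlated most with Model 4 (r = 0.9823 across genes), which lies on the other side of that split. For genes changed the opposite way the real count was 0 too, so that 100 of 100 groupings of the 12 libraries reach it by construction (highest other 0), which says nothing about chance. For the list counts chance cannot be excluded: 14 of 35 splits in Model against Control (28, highest other 39), 17 of 35 in HBG against Model (26, highest other 38) and 22 of 35 in HBG against Control (24, highest other 35) gave as many.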
